A study of Mus musculus with 6 samples.

How the data were processed

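RNA from forelimb autopods of mouse embryos at stage E11.5 was measured on 6 Agilent 8x60K arrays with 62976 spots each. Cells of Sox9-EGFP knock-in embryos on a C57BL/6 background had been sorted into Sox9-EGFP positive and Sox9-EGFP negative cells, with 3 samples per group. Per the labels, each sample came from about 10 autopods, and the amount of RNA is given as 100 ng in the extraction protocol and 75 ng in the labelling protocol. Whether the samples came from different litters or sorts, and the gates of the sort, are not given in the sources used here. The p-values therefore measure the spread between these samples.

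Per the file headers, the intensity values of each array were made by the authors with Feature Extraction 10.7.3.1, which corrects each spot for background and spatial trends within the array and does not normalize between arrays. The deposited series matrix holds log2 values that the authors normalized between arrays by quantiles, since every column has the same median of 6.41, minimum of 5.65 and maximum of 18.7. The background correction behind these log2 values is not given in the sources used here. Their correlation with the log2 mean signal was 0.997 to 0.998.

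The processed intensities were taken as log2 values relative to the 75th percentile of the 59305 non-control spots of each array. The 3671 control spots were left out. Replicate spots of 432 probes were averaged, with a coefficient of variation of 3.23% to 4.32% between them, leaving 55681 probes. Probes were named through their transcript accession (26300), their current symbol (2044) or a unique older symbol (355) in a table of mouse RefSeq genes, and the 26982 probes without a reference gene were not used in the gene comparison. Probe coordinates are those of mm9 in the files. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which left 26490 probes, of which 17 were left out because of outlier spots. The brightest probe stood for each gene, giving 13197 genes, of which 11763 were above background on all 6 arrays. Of the 3675 genes with several probes, 3 had probes called in opposite directions.

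Groups were compared with limma 3.58.1 in R 4.3.3 (linear model, moderated t statistics, Benjamini-Hochberg adjustment, threshold 0.05). The smallest exact p that 3 against 3 arrays can give is 0.1, so these calls rest on the variance that limma shares between genes. Gene lists were written from general knowledge, 27 lists with 491 members of which 372 were measured (364 distinct genes), and each list with at least 5 measured genes was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Lists are given by their number of called genes adjusted over all genes, and adjusted over the list alone where that differs. The headers give the slide of each array, and each of the 3 slides held 1 array of each group, so slide was also fitted as a block. Correlation between arrays was 0.971 to 0.993 within the positive group, 0.987 to 0.995 within the negative group and 0.939 to 0.963 between groups, and the first principal component held 66.1% of the variance.

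Genes are named in the text by a rule. Sox9 comes first, then the 10 largest differences in each direction. These were taken among called genes without overlap between the groups and above background on all arrays of the higher group. Next come 21 BMP, Wnt, FGF and Hox genes, chosen here for the Bmp, Sox9 and Wnt network of the title. In each list, up to 4 members with the smallest adjusted p follow and, for other cell types, the 2 brightest. All other named genes and probes were chosen after their values were seen, namely the largest differences measured in both groups, the remaining called list members, the Hox genes, members of gene families, Tcf7l2, and the intergenic probes with the genes nearest to them.

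The comparison, its tests, the gene lists and the alternatives were fixed before the data were examined, except that keeping names without a reference match was chosen after seeing the data. The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization, centring on the median of the tested genes, the series matrix values, no filter on background, a filter on all 6 arrays, the mean of a gene's probes, trend and robust moderation, array quality weights, slide and replicate blocks, a threshold of 0.01, a 2-fold limit, and leaving out each array in turn. Where an array was left out, the variance was estimated from the remaining 5.

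The pipeline was tested on simulated data with 13197 genes and 3 arrays per group. Of 50 genes changed by each fold it recovered 16% at 1.5-fold, 60% at 2-fold, 86% at 4-fold and 94% at 8-fold, and 8 of the 136 called genes were unchanged ones. Only 200 simulated genes were changed, a far smaller share than the 35.0% of genes called in the real data. The adjustment is stricter when fewer genes change, so these rates do not give the recovery in the real data. A raised list among 27 lists of 15 genes had adjusted p = 1.7e-27, or 0.00760 with an estimated correlation, and 0 unchanged lists were called. The simulated genes varied independently, so this does not show how often camera calls unchanged lists whose members are correlated. In the real data the cell cycle list, for 1, had an estimated correlation of 0.32. Input was read with the R packages data.table (version 1.17.8) and jsonlite (version 2.0.0), and figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Control spots, other than a check of spike-in brightness, and raw images were not used here. Results on some genes are left out of the text.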

Results

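Gene expression was measured in mouse forelimb autopods, the hand plates in which the digits form, at stage E11.5. The embryos carried EGFP knocked into the Sox9 locus, and their mesenchymal cells were sorted by flow cytometry into Sox9-EGFP positive and Sox9-EGFP negative cells. Sox9 encodes the transcription factor that starts cartilage formation and marks the condensing digit primordia. Each group had 3 samples, each made from about 10 autopods and hybridised to its own 1-colour Agilent array. The title of the series places the comparison in a patterning network of Bmp, Sox9 and Wnt, so the question was which genes, those of the BMP and Wnt pathways first, differed between the cells with and without the Sox9 reporter. The 75th percentile of the signal lay between 385 and 478 on 5 arrays and at 126 on the array of positive replicate 1, on which 24743 spots were well above background against 29800 to 35277 on the others. The number of arrays limits the precision of every value given here.

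Sox9 itself was 20.7-fold higher in Sox9-EGFP positive cells, a log2 difference of 4.37 ± 0.19 (SE, n = 3 per group; adjusted p = 0.000146, limma). Col2a1, the main collagen of cartilage, was 36.5-fold higher, and Bmpr1b, the type I BMP receptor of digit condensations, was 8.95-fold higher. Bmp4 was 18.7-fold lower, Bmp2 was 4.44-fold lower, and Msx1, a homeobox gene induced by BMP, was 23.7-fold lower in the positive cells. Axin2 and Lef1, which are induced by beta-catenin in the Wnt pathway, were 5.58-fold and 4.68-fold lower. All of these differences were past the threshold of the limma test and had the same sign on each of the 3 slides.

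The Sox9 probe, a 60-base oligonucleotide at chromosome 11, 112648809 to 112648868 of the mm9 build, gave 3.52, 2.99 and 3.60 on the positive arrays, in log2 units above the 75th percentile of each array. It lay between −1.13 and −0.88 on the negative arrays. Within the slides, each of which held 1 array of each group, the Sox9 difference was 4.52, 4.12 and 4.48, and with slide as a block its adjusted p was 0.000935.

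Of 13197 genes tested, 4617 (35.0%) passed the adjusted p threshold of 0.05 in limma, 1400 higher and 3217 lower in the positive cells. The median of all tested genes lay at a log2 difference of −0.18 under the 75th percentile scaling, so a gene's difference relative to all genes is its value less −0.18. Medians of lists within slides, with bounds or under other settings are given without that subtraction. Among the called genes 69.7% were lower, and this share was 54.7% with each array centred on the median of the tested genes, 53.7% after quantile normalization, 53.8% after normexp and quantile normalization and 55.4% in the authors' own values. At least 2-fold differences were carried by 1454 of the called genes, 702 higher and 752 lower. At least 4-fold differences were carried by 387, of which 228 were higher and 159 lower. In 6767 genes (51.3%) the 3 arrays of one group all lay above the 3 of the other, where chance gives 10%. The number of called genes fell to 2911 without positive replicate 3, to 2542 without negative replicate 1 and to 2485 without negative replicate 3. With slide as a block it was 5245. Every called gene had the same sign on all 3 slides, which follows by itself for the 4616 called genes without overlap between the groups.

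**Figure D1:**
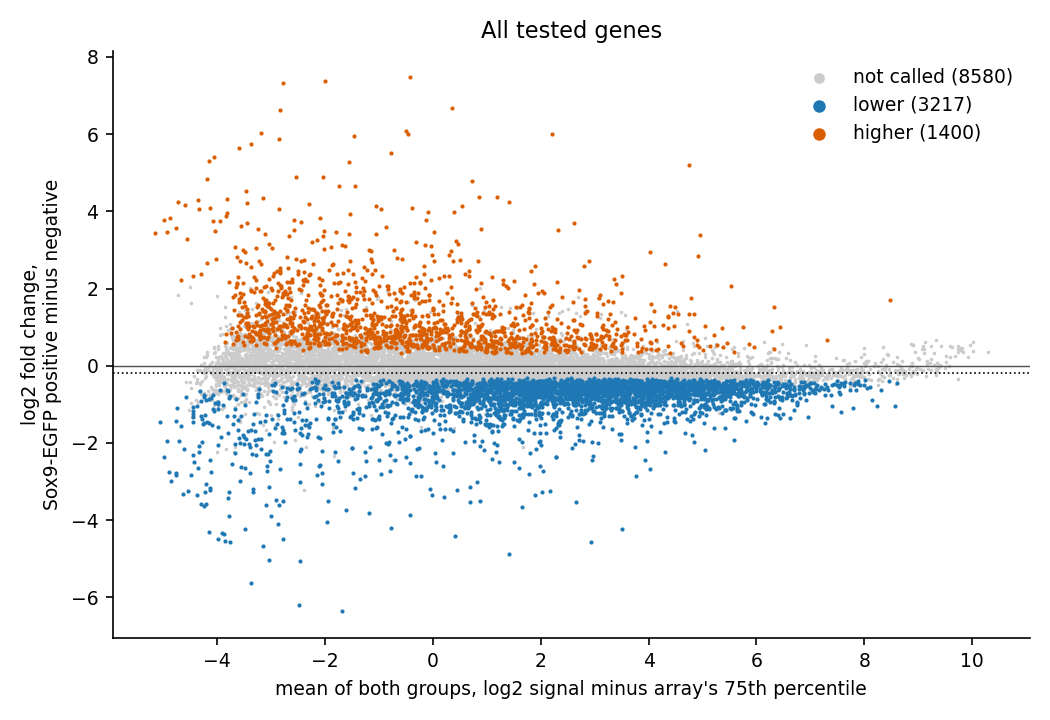
Log2 difference (positive minus negative, vertical axis) of each of the 13197 tested genes against its mean log2 signal over the 6 arrays (horizontal axis, relative to each array's 75th percentile). Points are genes, 1400 called higher, 3217 called lower and 8580 not called, and the cloud of all genes is centred on −0.18.

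Among the 10 largest fitted differences in the positive direction were those of 4 transcription factors, whose sizes rest in part on negative arrays near background. Foxc1, a forkhead factor of skeletal precursors, was higher by 7.47 ± 0.39 (SE, n = 3 per group), and Eomes, a T-box factor, by 7.38 ± 0.64. The homeobox gene Gsc was at least 44.8-fold higher and Ebf2 was higher by 5.95. Col9a2, a chain of the cartilage collagen IX measured on all 6 arrays, was higher by 6.67 ± 0.35. Cxcl12, a chemokine, and Fibin, a secreted factor of early limb buds, were each higher by 6.00. The chemokine Cxcl10 was at least 33.9-fold higher, Mgll, a monoacylglycerol lipase, at least 21.5-fold, and the filamin-binding Rflna was higher by 6.09. "At least" marks a gene that was not well above background on any array of the dimmer group, for which the dim group was set at the lowest signal well above background on each of its arrays, or at the gene's own value if that was higher. This level was −2.73 on the dim array of positive replicate 1 and −4.77 to −4.53 on the others, which makes the bounds of genes lower in the positive cells small. Foxc1 and Ebf2 were well above background on 2 of the 3 negative arrays and Eomes on 1. Among genes measured on all 6 arrays, which were added after the values were seen, Enpp2 was higher by 4.78, Irx1 by 4.66 and Rab32 by 4.37.

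In the negative direction, the ephrin receptor gene Epha8 was at least 47.0-fold lower in the positive cells, and Cstdc5, a gene of the cystatin family, at least 25.6-fold. Pf4, a platelet chemokine, was at least 11.4-fold lower, the long non-coding RNA Rmst at least 11.8-fold, and Vgll2, a cofactor of muscle genes, at least 9.57-fold. Dlx2 was at least 5.97-fold lower, and Shh, the signal of the posterior limb bud, at least 5.63-fold. Cck, a peptide hormone gene, had a log2 difference of −5.06 ± 0.78 and was above background on 1 of the 3 positive arrays. Ngfr, the low-affinity neurotrophin receptor, had −4.89 ± 0.13, and Msx1 had −4.56 ± 0.46 (SE, n = 3 per group). Among genes measured on all 6 arrays, Dync1i1 had −3.50, Apod −3.39 and Cygb −3.35. The rule took only genes past the limma threshold without overlap between the 3 arrays of each group, so these traits of the 20 genes are no further support. The same sign on all 3 slides follows from the lack of overlap. Their largest limma adjusted p was 0.00499, for Cck.

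Genes of cartilage matrix and its Sox factors were mostly higher in the positive cells. Of 16 measured members of this list, 11 were higher and 1 lower (13 and 1 adjusted over the list alone). Sox9, whose reporter the cells were sorted on, is among the 11 higher members and enters the median and the tests. Its direction was set by the sort, and the list was not tested without it. The median log2 difference of the list was 2.44, which is 2.62 above that of all genes. It was 2.13 with members not above background in 1 group at their bound. The size of this median fell to 0.96 under normexp and to 0.94 in the authors' values, with 11 higher and 1 lower member in each. Sox6, a partner of Sox9, was at least 12.3-fold higher, while Sox5 had a log2 difference of 0.32 ± 0.27 and was not called. Col9a1 was higher by 2.63 ± 0.14 and Matn4, a matrix matrilin, was 8.01-fold higher, and Cnmd (chondromodulin) was at least 4.01-fold higher. Acan, the core protein of aggrecan, had 0.58 ± 0.44 and was not called. The 1 lower member was Hapln1, a hyaluronan and proteoglycan link protein, which was at least 1.68-fold lower. Within the slides the list median was 2.31, 2.31 and 2.69. The camera test of the list against all other genes gave adjusted p = 3.20e-11, and 4.03e-10 with slide as a block. The call was lost at adjusted p = 0.266 with an estimated correlation.

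Regulators of mesenchymal condensation and early skeleton were higher in 8 and lower in 2 of 19 measured members (9 and 2 adjusted over the list alone). Foxc1 and Foxc2 (3.47 ± 0.20), Bmpr1b (3.16 ± 0.19) and Nkx3-2, a homeobox gene of early chondrocytes (2.75 ± 0.16), were the members with the smallest p among those that were higher. The 2 lower members were Prrx2, a homeobox gene of undifferentiated limb mesenchyme (−1.93 ± 0.11), and fibronectin, Fn1 (−0.60 ± 0.13). The Fn1 call was lost without positive replicate 3, negative replicate 1 or negative replicate 3, with adjusted p = 0.0529, 0.0606 and 0.0634, and after quantile normalization (0.192). Its median was 0.66, or 0.83 above all genes, and 0.71, 0.76 and 0.37 within the slides. Camera gave adjusted p = 0.00107, 0.00144 with slide as a block, and adjusted p = 0.511 with an estimated correlation.

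Of 17 measured BMP ligands and secreted antagonists, 4 were higher and 7 lower, with ligands and antagonists on both sides. The ligands Bmp2 (−2.15 ± 0.20), Bmp4 (−4.22 ± 0.13) and Bmp7 (−1.02 ± 0.14) were lower in the positive cells, as were the ligands Bmp5 (−1.44) and Gdf6 (−0.89) and the antagonists Grem1 (−1.58) and Fst (−1.50). Bmper and Chrdl1, extracellular modulators of BMP, were higher by 3.21 ± 0.32 and 2.73 ± 0.21, and the ligands Gdf7 and Gdf5 were higher by 1.25 and 1.25. Nog, the BMP antagonist of cartilage, had 0.73 ± 0.48 and was not called (adjusted p = 0.279), but was called at 0.0278 with slide as a block. The Gdf5 call, of a gene known from joint formation, was lost without positive replicate 3 (adjusted p = 0.0900), and without negative replicate 1, 2 or 3, where the largest was 0.103. The Fst call was lost without any array but negative replicate 3 (0.0857 to 0.136), and the Bmp5 call without positive replicate 2 or negative replicate 1, 2 or 3 (0.0598 to 0.0850). The list median was −0.20 and its mean −0.22, while camera, which ranks the list against all other genes, gave the direction up with adjusted p = 0.931. Its median lay at −0.02 relative to all genes, and the median of −0.20 became 0.22 with only the genes above background on all 6 arrays. The fry test, which asks whether the members move 1 way on balance, gave the direction down with adjusted p = 0.0152.

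Of 14 measured BMP receptors and Smads, Bmpr1b and Acvrl1 (1.80 ± 0.23) were higher and 0 lower. Rgma, a BMP co-receptor, had 0.51 ± 0.20 and was not called (adjusted p = 0.0929), but was called at 0.0290 with slide as a block. Bmpr1a had 0.08 ± 0.13, Smad1 −0.25 ± 0.21 and Smad4 −0.13 ± 0.14, none of them called. At −0.09, the list median lay 0.09 above all genes (camera adjusted p = 0.152), and it was 0.21 after quantile normalization (0.0751). Among 13 measured genes commonly induced by BMP signalling, 1 was higher and 4 lower, with a median of −0.29 relative to all genes (camera adjusted p = 0.435). Before that subtraction the median was −0.47, and −0.70 without positive replicate 1. The higher gene was Id4 (1.29 ± 0.16). The lower genes were the homeobox genes Msx1, Msx2 (−3.34 ± 0.41) and Dlx5 (−2.43 ± 0.37), and Hand1, at least 1.47-fold lower, whose call was lost without positive replicate 3 (adjusted p = 0.0514) or negative replicate 1 (0.0556). Id1 had −0.37 ± 0.19 and was not called. Of 13 measured TGF-beta and activin genes, 4 were higher and 0 lower. They were Inhba, a subunit of activin (11.3-fold), Tgfbr3 (1.82 ± 0.16), Inhbb (1.13 ± 0.18) and Tgfb2 (0.99 ± 0.21). The Inhbb call was lost after quantile normalization (largest adjusted p = 0.137), and the Tgfb2 call without negative replicate 1 (0.0516) or negative replicate 3 (0.0610). Camera gave the TGF-beta list adjusted p = 0.0284, 0.0302 with slide as a block, and adjusted p = 0.481 with an estimated correlation. Its median was 0.31 above that of all genes, and the call was lost at adjusted p = 0.160 with no filter on background and at 0.0538 with the genes above background on all 6 arrays.

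Genes commonly induced by beta-catenin were lower in the positive cells in 9 of 14 measured members, and none was higher. Beside Axin2 (−2.48 ± 0.20) and Lef1 (−2.23 ± 0.15), the transcription factor Tcf7 was lower by −2.14 ± 0.16 and the receptor Tnfrsf19 by −2.48 ± 0.22. The median of the list was −1.97, or −1.79 relative to all genes, and −1.83 or lower within each slide. Camera gave adjusted p = 0.0113, 0.0211 with slide as a block, and adjusted p = 0.389 with an estimated correlation. With only the genes above background on all 6 arrays the median was −0.93 and the call was lost (adjusted p = 0.0801). Axin2 and the secreted Wnt antagonist Dkk1 were above background on 2 of the 3 positive arrays.

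Wnt antagonists split between higher and lower genes. Of 10 measured, Sfrp1 (2.15 ± 0.15), Sfrp2 (1.89 ± 0.15), Sostdc1 (1.64 ± 0.20), Frzb (1.36 ± 0.30) and Dkk3 (0.43 ± 0.10) were higher, and Wif1 (−3.67 ± 0.15), Dkk1 (−3.51 ± 0.42) and Kremen1 (2.0-fold) were lower. The Frzb call was lost without positive replicate 2 (adjusted p = 0.0501) or negative replicate 1 (0.0510), the Dkk3 call without any array but positive replicate 1 (0.0511 to 0.0840), and the Kremen1 call with the mean of its probes (0.191). These antagonists had a median of 0.75 and a mean of −0.03, both before the median of all genes is taken off, and camera gave the direction up with adjusted p = 0.152. Of 18 measured Wnt receptors and R-spondin modulators, 4 were higher and 4 lower (6 and 4 adjusted over the list alone). The frizzled receptors Fzd9 (2.38 ± 0.16), Fzd2 (1.37), Fzd8 (1.36) and Fzd5 (at least 6.77-fold) were higher. Fzd10 (−3.52 ± 0.13), Fzd1 (−0.45) and the R-spondins Rspo4 (at least 5.13-fold) and Rspo1 (at least 1.64-fold) were lower. Leaving out negative replicate 3 ended the call of Fzd8 (adjusted p = 0.0530), as did quantile normalization (0.0534), and leaving out positive replicate 3 that of Rspo1 (0.0536). The call of Fzd1 ended without positive replicate 2 or 3 or negative replicate 1 or 3 (0.0650 to 0.0872), under each of the 4 other scalings (0.0718 to 0.277) and with no filter on background (0.0931), which also ended that of Fzd5 (0.0616). The median of this list was 0.37 above all genes, with camera up (adjusted p = 0.185) and fry down (0.266).

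Only 6 of 19 Wnt ligands were measured. Wnt16 was at least 3.23-fold higher and Wnt9a, a ligand of joint regions, was higher by 1.71 ± 0.35, while Wnt5b was lower by −0.40 ± 0.12. The Wnt9a call was lost without negative replicate 3 (adjusted p = 0.0544), and the Wnt5b call without any array but positive replicate 1 (0.0936 to 0.151) and with slide as a block (0.0617). Wnt5a had −0.29 ± 0.18 and Wnt11 0.23 ± 0.19, neither of them called, and beta-catenin itself, Ctnnb1, had −0.07 ± 0.10 (adjusted p = 0.663). Wnt3 and the FGF feedback gene Spry4 were not well above background on any array and were not tested. The median of the ligands was 0.48 above all genes (adjusted p = 0.202).

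**Figure D2:**
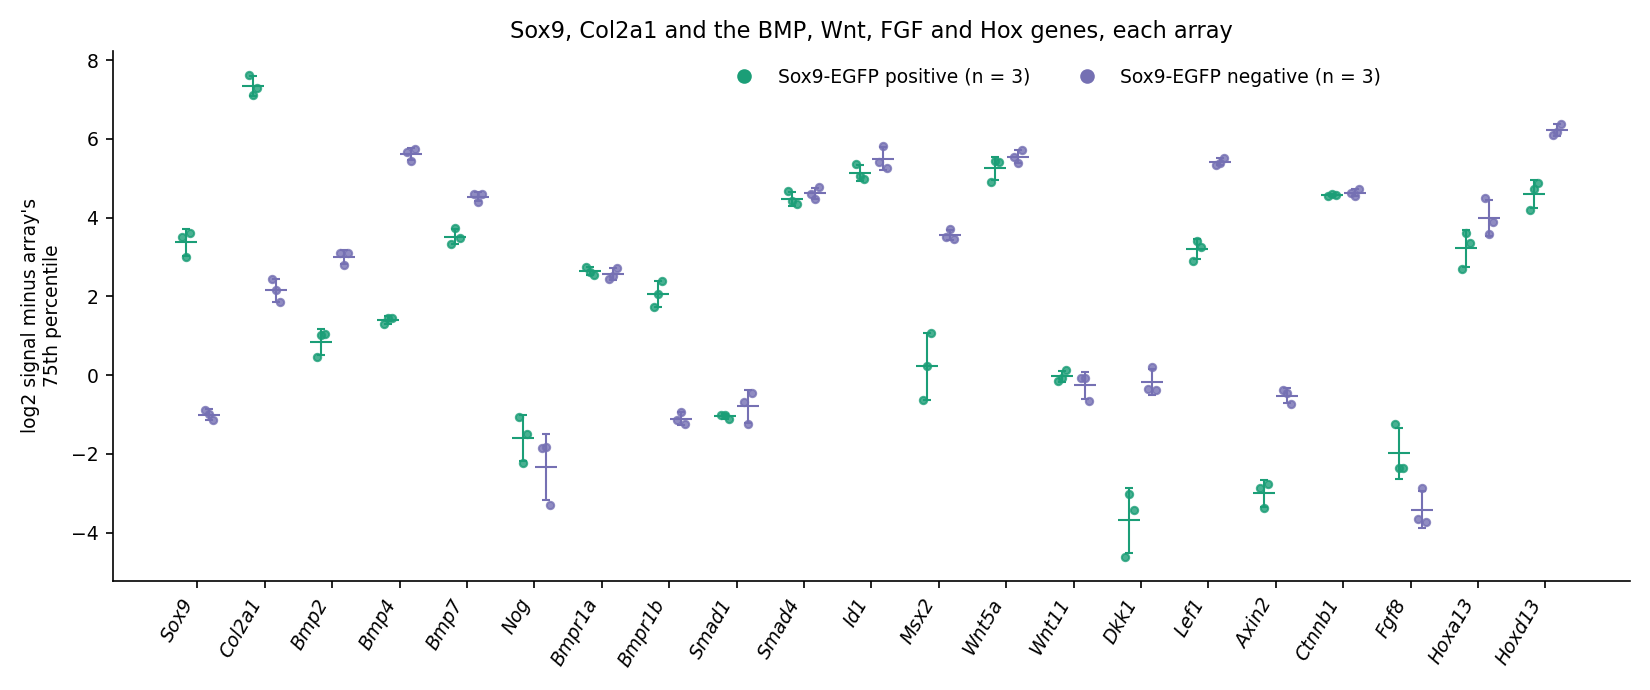
Log2 signal relative to the array's 75th percentile (vertical axis) in 3 positive and 3 negative arrays for each gene. The genes are Sox9, Col2a1 and members of the BMP, Wnt, FGF and Hox groups. Points are arrays and bars give the mean ± SD. Sox9 lay between 2.99 and 3.60 on the positive arrays and at −0.88 or below on the negative ones, and Bmp4 lay between 1.29 and 1.46 on the positive arrays against 5.43 to 5.74 on the negative ones.

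Of 17 measured FGF genes, 5 were higher, 6 lower and 6 not called. The receptors Fgfr3 (1.93 ± 0.14), Fgfr2 (1.37), Fgfr1 (0.56) and Fgfr4 (0.69) and the ligand Fgf8 (1.43 ± 0.38) were higher. The 6 lower genes included the feedback and target genes Spry1 (−2.80 ± 0.23), Etv4 (−2.68 ± 0.23) and Etv5 (−1.49 ± 0.22) and the ligand Fgf10 (−1.34). Adjusted over the list alone, 5 were higher and 8 lower. The Fgfr4 call was lost without positive replicate 3 (adjusted p = 0.0706), negative replicate 1 (0.0759) or negative replicate 3 (0.0810), and that of Fgf8 without the same arrays (0.0523, 0.0977 and 0.106). The call of Fgf8 was also lost under normexp (0.0562), in the authors' values (0.0537) and with no filter on background (0.0841). FGF genes had a median of −0.52, or −0.34 relative to all genes (camera adjusted p = 0.994). Without that subtraction it was 0.04, −0.54 and −0.73 within the slides. It was −0.86 without positive replicate 1, where 5 genes were higher and 9 lower. With no filter on background it was 0.16, where the median of all genes was 0.10.

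Among 12 measured hedgehog genes, 4 were higher and 3 lower. The pathway targets Hhip (2.05 ± 0.12) and Ptch1 (0.89 ± 0.12), the co-receptor Boc (2.02 ± 0.12) and the factor Gli2 (1.45) were higher, while the ligand Shh and the genes Smo (−0.37) and Gas1 (−0.46) were lower. The Smo call was lost without any array but negative replicate 2 (adjusted p = 0.0646 to 0.141) and its sign turned after quantile normalization, and the Gas1 call was lost without any 1 array (0.0551 to 0.134). With slide as a block neither Smo (0.0555) nor Gas1 (0.0606) was called. Hedgehog genes had a median 0.27 above all genes and camera gave adjusted p = 0.0672, with 0.0256, 0.0463 and 0.0255 under normexp, quantile normalization and the authors' values, and adjusted p = 0.511 with an estimated correlation. Among 12 measured Notch genes, Hes5 (1.32), Notch1 (1.02), Dll3 (1.21), Notch4 (0.49) and Notch2 (0.48) were higher. Hey1, a target of Notch and BMP signals, was lower (−2.45 ± 0.18), as was Rfng (−0.42). Hey1 kept its call without each array in turn. Hes5 lost its call without negative replicate 3 (adjusted p = 0.0508) and Notch1 without negative replicate 1 (0.0505), while the calls of Dll3, Notch2, Notch4 and Rfng were each lost without 4 of the 6 arrays, negative replicates 1 and 2 among them (0.0542 to 0.130). The Notch list median was 0.62 above all genes (camera adjusted p = 0.0672, 0.0257 with slide as a block, and adjusted p = 0.481 with an estimated correlation).

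In retinoic acid metabolism, Aldh1a2, the enzyme that makes retinoic acid, was 11.4-fold higher in the positive cells (3.52 ± 0.40), and Cyp26b1, the enzyme that degrades it, was 2.52-fold lower (−1.33 ± 0.19). The receptor Rarb (1.26 ± 0.20), Dhrs3 (0.83 ± 0.11) and Crabp2 (0.66) were also higher, and Crabp1 (−1.11) and Stra6 (−0.79) lower, 4 higher and 3 lower of 15 measured. The calls were lost without negative replicate 3 for Crabp2 (adjusted p = 0.0542) and Crabp1 (0.0546), and without negative replicate 1 for Crabp1 (0.0664) and Stra6 (0.0673). Retinoic acid genes had a median of −0.04, or 0.14 above all genes (camera adjusted p = 0.338), and 0.23 after quantile normalization (0.179).

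Posterior Hox genes, which pattern the limb from shoulder to digits, were higher in 3 and lower in 2 of 11 measured members. Hoxa11 (1.61 ± 0.27), Hoxd9 (1.40 ± 0.15) and Hoxd8 (1.34 ± 0.19) were higher. Hoxd13 (−1.61 ± 0.20) and Hoxd12 (−0.77 ± 0.15) were lower, and the Hoxd12 call was lost after quantile normalization (largest adjusted p = 0.184). Hoxa13 had −0.76 ± 0.32 and was not called at adjusted p = 0.108, but was called at 0.0367 with slide as a block. In the other direction, Hoxc10 had 1.92 ± 0.79 and was not called (0.106), but was called at 0.0438 with slide as a block. Posterior Hox genes had a median 0.40 above all genes (camera adjusted p = 0.0972). Among 24 other limb patterning factors, 7 were higher and 10 lower. The AP-2 factors Tfap2c (−3.52 ± 0.19) and Tfap2a (−2.66 ± 0.14) and the LIM homeobox genes Lhx2 (−2.19 ± 0.14) and Lhx9 (−1.93 ± 0.13) were lower, while Sall1 (1.52), Sall3 (1.32) and Tbx5 (1.02), the T-box factor of the forelimb, were higher. Camera gave this list adjusted p = 0.724 and its median was −0.40 relative to all genes.

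Tendon, dermal and connective tissue genes were higher in 9 and lower in 5 of 17 measured members (9 and 6 adjusted over the list alone). Postn (periostin) was at least 4.27-fold higher, and the small proteoglycans Dcn and Lum were higher by 1.84 and 1.83. Scx, the factor of tendon progenitors, was higher by 1.34. The 5 lower members were the homeobox gene Mkx (−2.80 ± 0.25), Twist2 (−2.06 ± 0.20), Twist1 (−1.92 ± 0.13), Col3a1 (−2.13) and Tcf4 (−0.72). Tcf4 was measured under its own symbol. The same name is in use for Tcf7l2, a gene outside the list that was looked at after the values were seen and was higher by 1.57 ± 0.22. The Col3a1 call was lost without any array but positive replicate 1 (adjusted p = 0.0549 to 0.0715). Connective tissue genes had a median of 1.06, or 1.24 above all genes (camera adjusted p = 0.0672). Without that subtraction it was 1.28, 1.22 and 0.66 within the slides and −0.07 with only the genes above background on all 6 arrays, where the median of all genes was −0.19.

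Eph receptors and ephrins, which guide cell sorting, held 3 higher and 5 lower genes among 19 (4 and 5 adjusted over the list alone). Efna1 (2.70 ± 0.17), Efna5 (1.09 ± 0.14) and Epha7 (0.68) were higher. Epha8, Epha2 (−1.57 ± 0.16), Epha4 (−1.01), Ephb2 (−0.62) and Ephb4 (−0.39) were lower. The calls of Epha7 (adjusted p = 0.0534 to 0.0956), Ephb2 (0.0645 to 0.114) and Ephb4 (0.0727 to 0.155) were lost without most single arrays, negative replicates 1 and 2 and positive replicate 3 among them, and those of the Ephb genes with slide as a block. The list median was −0.18, or level with all genes, while camera gave up (adjusted p = 0.720) and fry down (0.0394). After quantile normalization the median turned to 0.18.

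Cell cycle genes were lower in 12 of 27 measured members (13 adjusted over the list alone), and none was higher. The called genes with the smallest adjusted p were E2f1 (−1.25 ± 0.16) and Mcm3 (−0.88 ± 0.12), Mcm5 (−0.82 ± 0.10) and Mcm2 (−0.78 ± 0.10) of the replicative helicase. The median was −0.36, or −0.18 relative to all genes, and −0.47, −0.24 and −0.65 within the slides. Camera gave adjusted p = 0.00349, 0.00478 with slide as a block, and adjusted p = 0.511 with an estimated correlation. The list held 7 lower genes and lost its call under quantile normalization (0.107), normexp (0.106) and the authors' values (0.0942), and held 10 lower genes with the arrays centred on the median. Hypoxia and glycolysis genes were lower in 10 of 18, among them the glycolytic enzymes Hk2 (−2.25 ± 0.20), Aldoa (−1.20 ± 0.10), Ldha (−1.04 ± 0.12) and Pgk1 (−0.95 ± 0.13). The other lower genes, Slc2a1, Bnip3, Pdk1, Ankrd37, P4ha1 and Eno1, each lost the call without at least 1 array (limma adjusted p = 0.0501 to 0.136). Egln3 (0.74) and Ndrg1 (0.77) were higher, of which Egln3 lost its call after quantile normalization (largest adjusted p = 0.122) and Ndrg1 without any 1 array (0.0556 to 0.126). The hypoxia list had a median of −0.28 relative to all genes (camera adjusted p = 0.119), and 6 lower genes after quantile normalization. Of 12 immediate early and heat shock genes, which respond to cell dissociation, Jun was higher by 2.95 ± 0.21 and 5 were lower. The lower genes were Egr1 (at least 3.17-fold), Hsph1 (−1.25 ± 0.19), Hspb1 (−0.96 ± 0.12), Dusp1 (−0.61) and Dnajb1 (−0.52). The Dusp1 and Dnajb1 calls were lost without positive replicate 3, negative replicate 1 or negative replicate 3 (adjusted p = 0.0539 to 0.138), and that of Dnajb1 also without positive replicate 2 and with slide as a block. The median of the 12 genes was −0.26 relative to all genes (camera adjusted p = 0.410). Before that subtraction it was −0.44, and −0.68 without positive replicate 1.

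Markers of other cell types were measured beside these groups. Genes of migrating muscle precursors were lower in the positive cells in 7 of 10 measured members (8 adjusted over the list alone). Pax3, the factor of muscle precursors, was at least 4.19-fold lower, Chrna1 at least 3.94-fold, and Lbx1 had −3.60 ± 0.39 with 1 of the 3 positive arrays above background. Chrna1 lost its call without negative replicate 1 (adjusted p = 0.0505) or 3 (0.0531), Cdh15 (−1.26) without negative replicate 1 (0.0580), and Actc1 (−3.60, above background on 1 of the 3 positive arrays) without negative replicate 1 (0.0895) or 2 (0.0778). Myod1 (at least 1.80-fold lower) and Myog (at least 2.15-fold) each lost it without positive replicate 2 or 3 or negative replicate 1 or 2 (0.0566 to 0.115). Eya1, the brightest member, had −0.30 ± 0.29 and was not called. The list median was −2.78, or −2.60 relative to all genes. Without that subtraction it was −1.18 with members at their bound, and −1.76, −2.17 and −3.14 within the slides. Camera gave adjusted p = 0.0672, 0.0322 with slide as a block and adjusted p = 0.511 with an estimated correlation. It gave 0.0146 without positive replicate 1, 0.00733 without negative replicate 3 and 0.0361 with arrays centred on the median. The list was not called when any of the other arrays was left out (0.0666 to 0.137). Nor was it called with no filter on background (0.110) or with slide as a random block (0.0772).

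Genes listed for limb ectoderm, which lies outside the mesenchyme, held 4 higher and 1 lower of 10 measured (5 and 1 adjusted over the list alone). The higher genes were Krt18 (2.59 ± 0.12) and Krt8 (1.22 ± 0.13), keratins of simple epithelia, Trp63 (1.01 ± 0.29), a factor of stratified epithelia, and Fgf8, the signal of the apical ridge. Grhl3 was lower (−0.88 ± 0.12), and Epcam and Krt14, further epithelial markers, had −0.43 ± 0.22 and −0.03 ± 0.27 and were not called. The Trp63 call was lost without positive replicate 2 or any 1 negative replicate (adjusted p = 0.0501 to 0.126). The list median was 0.70, or 0.88 above all genes. Without that subtraction it was 1.14, 0.76 and 0.13 within the slides, 0.29 without positive replicate 1 and 0.23 under normexp. Camera gave adjusted p = 0.0409, 0.0322 with slide as a block and adjusted p = 0.511 with an estimated correlation, and the call was lost without positive replicate 1 (0.103), without negative replicate 3 (0.0809) and under each of the 4 other scalings (0.0984 to 0.246).

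Endothelial markers held 1 lower gene of 7 measured, Egfl7 (−0.71 ± 0.13), whose call was lost after quantile normalization (adjusted p = 0.0598), with a list median of −0.14 relative to all genes (camera adjusted p = 0.464). Among 8 erythroid genes only Gata1 was called, at least 1.62-fold lower, and 0 adjusted over the list alone. With slide as a block the hemoglobin genes Hbb-bt (−3.21, adjusted p = 0.00535) and Hba-a1 (−2.44, 0.0250) were called lower as well. The Gata1 call was lost without any array but positive replicate 1 (0.0683 to 0.131). The erythroid median was −1.23 relative to all genes (−1.15 with Gata1 at its bound and before that subtraction), with camera adjusted p = 0.506. Hemoglobin transcripts varied within the negative group, and the mean of the erythroid genes was 2.49 on negative replicate 2 against 0.18 and −0.62 on the other negative arrays and −1.67 to −0.00 on the positive ones. Macrophage, platelet and blood markers held 2 lower genes of 5, Pf4 and Cd14 (−0.41 ± 0.12), and their mean was 0.78 on negative replicate 2 against −1.85 and −2.43 on the other negative arrays. The Cd14 call was lost without any array but positive replicate 3 (0.0712 to 0.126) and with slide as a block (0.0556). The median of the 5 genes was −0.41, or −0.23 relative to all genes (camera adjusted p = 0.657). Without that subtraction it was −2.67, 0.96 and −0.19 within the slides and 0.68 without negative replicate 2. Schwann cell, melanoblast and nerve markers were split, with Sox10 (1.70 ± 0.43) and Stmn2 (0.92) higher and Dct (−1.73 ± 0.24) and Kit (−0.53) lower of 8. The calls of Sox10, Stmn2 and Kit were each lost without negative replicates 1 and 3 and at least 1 further array (0.0632 to 0.126), and the median was 0.31 above all genes (camera adjusted p = 0.410).

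**Figure D3:**
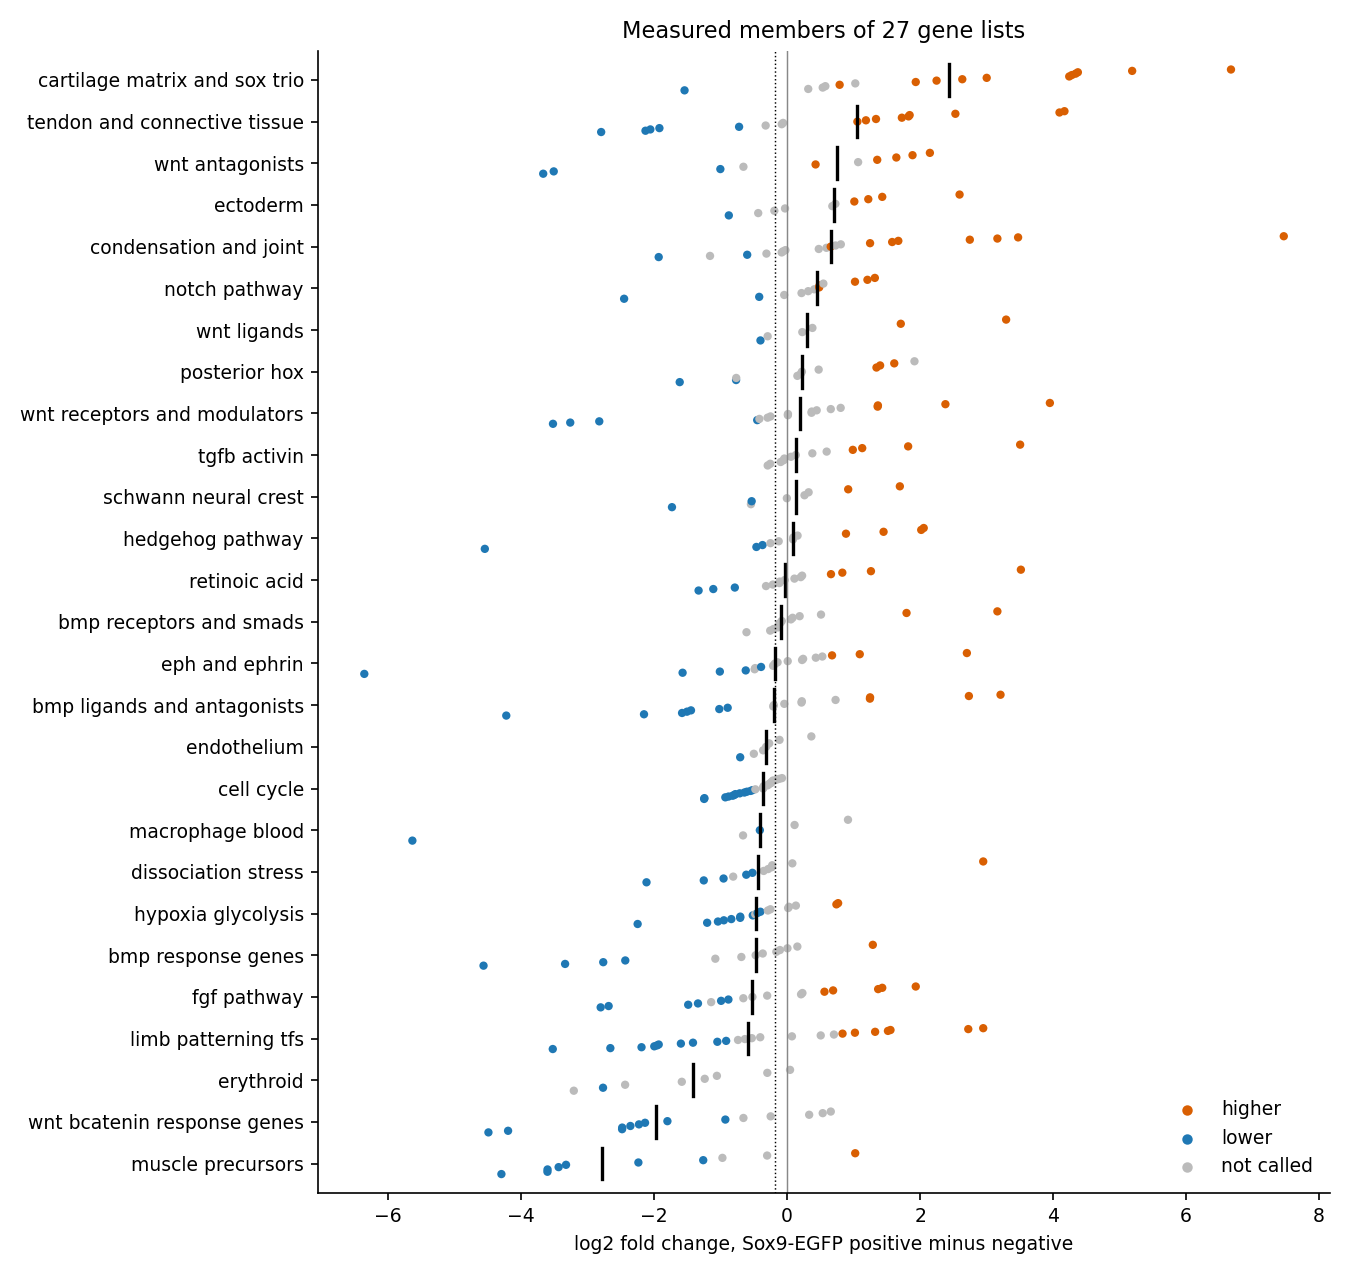
Log2 difference (positive minus negative, horizontal axis) of each measured member of the 27 gene lists (vertical axis). Points are genes, black bars are list medians and the dotted line is the median of all genes at −0.18. The highest list median is 2.44 for cartilage matrix and the lowest −2.78 for muscle precursors, which becomes −1.18 with members at their bound, above the −1.97 of beta-catenin response genes.

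Of the 27 lists, 6 passed the camera test at a preset correlation, namely cartilage matrix, condensation, TGF-beta and activin, beta-catenin response, cell cycle and ectoderm. None of these calls held with an estimated correlation, where the smallest adjusted p was 0.266. The counts of called genes were the same adjusted over the list alone in 17 of the 27 lists. Other ways of dividing the 6 arrays into 3 and 3 gave up to 6 lists past the same threshold. The number of lists called therefore does not set the real grouping apart. None of the other divisions gave a called gene. Each of them mixes positive and negative arrays, so the group difference adds to the spread within its sides. This lowers the count by itself, so the lack of called genes does not set the real grouping apart either. With slide as a block 8 lists passed, and fry called 17.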

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

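The tests on the share of lower genes, on muscle cells among the negative cells and on scaling for DNA replication genes were chosen after the result was seen.

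Probes for long intergenic RNA regions lie outside the gene comparison, and of 4722 such probes 632 passed the limma threshold, 391 higher and 241 lower in the positive cells. The nearest measured gene did not always move with a probe. A probe on chromosome 19 at 5834543 to 5834602 was higher, with 0.90 on the dim array of positive replicate 1 against −2.85 and −2.90 on the other positive arrays and −6.36 to −5.32 on the negative ones. Another on chromosome 18 at 36451920 to 36451979 was at least 2.78-fold higher, while the nearest genes Frmd8 (0.18 ± 0.11) and Pura (0.71 ± 0.41) were not called. The largest lower one, on chromosome 3 at 37891481 to 37891540, was at least 7.83-fold lower and lay 278 kb from Gm5148 (−0.69). A probe on chromosome 3 at 145314998 to 145315057 had a log2 difference of 3.07 ± 0.21 (SE, n = 3 per group) and was above background on 2 of the 3 negative arrays. It lay 4.81 kb from the probe of Ccn1, a matrix-associated gene that was higher by 2.71 ± 0.25. A probe on chromosome 17 at 80144297 to 80144356 was at least 4.61-fold lower, 37.8 kb from Cyp1b1, which had −2.15 ± 0.45 and lost its call without negative replicate 1 (adjusted p = 0.0524). A probe on chromosome 11 at 96125513 to 96125572 was at least 2.21-fold lower, 12.2 kb from Hoxb9, itself at least 5.05-fold lower. What these RNAs do was not analysed here.

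The real grouping gave 4617 called genes and the highest of the other splits gave 0, so 1 of the 10 splits had as many. Every other split mixes positive and negative arrays, which puts the group difference into the spread and lowers the count. The contrast of 4617 with 0 thus decides nothing. For gene lists the real grouping gave 6 and the highest of the others also 6, so 3 of the 10 splits had as many. With 10 splits the share is too large to fall under 0.05.

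More called genes were lower than higher. The share of lower genes was 54.7% with each array centred on the median of the tested genes and 68.3% without positive replicate 1, the dim array. The dim array alone is argued against by the second value. Centring on the median of the same genes sets the balance of higher and lower genes by itself, so the first value does not decide whether the 75th percentile scaling or a real difference in RNA content lies behind the excess. Both stay open.

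Muscle precursor genes were lower in the positive cells. Without the dim array 7 of the 7 called lower genes were still lower and called, and with median centring 6 of the 7, which argues against both as the whole cause, although 5 of the 7 (Chrna1, Cdh15, Myod1, Myog and Actc1) lost the call without at least 1 other array (adjusted p up to 0.115). Of 10000 random lists matched on mean signal, 0% had a median as low, but these lists ignore the correlation within the muscle list (camera adjusted p = 0.511 with it estimated) and say nothing of its source. Muscle precursor cells sorted with the negative cells and a lower level in mesenchymal cells themselves cannot be told apart here. The labels call all cells mesenchymal, the bright member Eya1 (−0.30) and Met (−0.97) were not called, and none of the 10 measured genes is in another list.

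DNA replication genes were lower in the positive cells, 9 of 9, against 3 of 18 genes of mitosis, a division of the cell cycle list made after the values were seen. Replication minus mitosis genes differed between the groups by −0.57 ± 0.12 (SE; exact permutation p = 0.1, the smallest possible), and by −0.36, −0.77 and −0.58 within the slides. Without the dim array it was −0.58 ± 0.15. A division chosen from these values cannot decide on the dim array or the scaling. The whole cell cycle list held 12 lower genes with and without the dim array, which argues against that array as the whole cause. With median centring 9 of the 9 were still lower and called. Such centring shifts all genes of an array alike, so a scaling effect that depends on signal stays open. The cell cycle list held 7 lower genes under quantile normalization, normexp and the authors' values. Mcm4 and Mcm6 lost their calls after quantile normalization (adjusted p = 0.0816 and 0.118), under normexp (0.0729 and 0.131) and in the authors' values (0.0522 and 0.119), and Mcm6 also without negative replicate 1 (0.0515). Since the same values chose the division and measured it, the difference between the 2 sets stays a hypothesis, and the cell cycle itself was not measured.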

How the results depend on the processing

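The setting that kept names without a reference match was chosen after the result was seen, and it called 4858 of 19448 names.

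Sox9 stayed past the threshold in every setting run. Leaving out 1 array gave 4.26 to 4.56 for Sox9, 2485 to 5176 called genes, 895 to 1643 higher and 1590 to 3533 lower, and 6 to 7 lists. It gave list medians of 2.34 to 2.52 for cartilage matrix, −0.22 to −0.20 for BMP ligands, 0.06 to 0.48 for Wnt ligands and −2.08 to −1.88 for beta-catenin response genes.

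Lower genes numbered 1886 under normexp, 1747 after quantile normalization and 1911 in the authors' values. Without a filter on background 2656 genes were called, 1574 of them lower. A threshold of 0.01 called 2109 (743 higher, 1366 lower), and a 2-fold limit 1454 (702 and 752). None of the genes called in the main setting was called in the opposite direction under another scaling or filter. Replicate numbers did not pair the arrays, since deviations from the group means correlated at −0.27, −0.42 and 0.16 by number against 0.46, 0.36 and 0.23 by slide. A replicate block called 2157 genes, 856 higher and 1301 lower. A fixed slide block called 5245, and a random slide block 5973, where the lists were tested with cameraPR on moderated statistics.

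With an estimated correlation 0 lists passed, with adjusted p = 0.266 for cartilage matrix (median 2.44) and 0.389 for beta-catenin response genes (median −1.97), and fry called 17, with 0.0152 for BMP ligands (median −0.20). Over all settings adjusted p ran from 3.44e-28 to 0.266 for cartilage matrix. Beta-catenin response genes had a median of −0.93 (adjusted p = 0.0801) with the filter on all 6 arrays. Muscle precursors had too few genes for a test under that filter.

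Besides Sox9, 247 called genes were chosen for naming, not all of which appear in the text. Of these, 171 kept their call in every setting that tested them and 76 lost it in at least 1. Without at least 1 array, 65 lost it. The filter on all 6 arrays tested only 223 of the 282 chosen genes, called or not, and genes absent there were not counted as lost. The stricter threshold and the fold limit were not part of this count. Smo changed sign, to 0.0014 after quantile normalization and 0.10 with the mean of its probes. Of 657 uncalled values, 37 changed sign. The cause was not tested.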

Other observations

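The test on Hox paralogue number was chosen after the result was seen, while those on symbol roots and neighbouring genes were planned.

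Genes of protein synthesis in mitochondria were lower in the positive cells. Of 48 Mrpl genes, which encode the large mitochondrial ribosomal subunit, 32 were lower and 0 higher, with a median of −0.36 relative to all genes (camera adjusted p = 1.08e-05, 0.855 with an estimated correlation), and 9 were lower after quantile normalization (0.00449). Mrps genes of the small subunit were lower in 23 of 29, and in 11 after quantile normalization. Mrpl12 had −1.14 ± 0.15 and Mrps18b −1.34 ± 0.12 (SE, n = 3 per group). Eif genes of translation initiation were lower in 31 of 54 (13 after quantile normalization), and Nup genes of the nuclear pore in 15 of 20 with 1 higher (5 and 1 after quantile normalization), led by Nup210 (−1.57 ± 0.15).

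Families of matrix genes moved the other way. Of 28 collagen genes 13 were higher and 4 lower, with a median of 0.60. Of 12 Adamts proteases 8 were higher and 1 lower, led by Adamts15, higher by 4.09 ± 0.22, and Arhgef exchange factors were higher in 8 of 22 and lower in 1. In all, 26 of 150 symbol roots with at least 10 genes passed the camera threshold and 0 with an estimated correlation. After quantile normalization the families named here still passed (camera adjusted p up to 0.0153, for Eif). Several other roots did not, among them Timm and Psmd (0.126 each) and Cyp (0.622), so the count depends on the scaling. Genes of these families may share regulation.

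Across the HoxD cluster the differences fell from 1 end to the other. Hoxd3 (3.53, above background on 1 of the 3 negative arrays), Hoxd4 (1.48), Hoxd8 (1.34) and Hoxd9 (1.40) were higher, Hoxd10 (0.21) and Hoxd11 (0.22) were not called, and Hoxd12 (−0.77) and Hoxd13 (−1.61) were lower. The Hoxd4 call was lost without any array but negative replicate 2 (adjusted p = 0.0627 to 0.0995). Over 25 measured Hox genes of all clusters, paralogue number and difference had a Spearman correlation of −0.11 (permutation p = 0.584, 100000 permutations), so the order did not hold across clusters. In the HoxC cluster Hoxc6 was higher by 3.04, and in the HoxB cluster Hoxb3 had −2.20 with 2 of the 3 positive arrays above background.

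Neighbouring genes moved together weakly. The differences of 13152 adjacent pairs correlated at 0.11, against at most 0.035 in 1000 shuffles, and 11202 pairs with different symbol roots more than 5 kb apart correlated at 0.081, against at most 0.042. Shared regulation of neighbours is 1 candidate explanation, and overlapping transcripts were not excluded.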
